A study of Mus musculus with 16 samples.

How the data were processed

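RNA from 16 mouse cell samples was measured on 16 Agilent 1-colour arrays of design 014868, 1 sample per array, with Cy3 as the dye, per the file headers. Per the labels, the samples were ES cells, Flk1+ mesoderm cells and ntTS cells (trophoblast stem cells derived after nuclear transfer), each wild type (WT) or lacking Dnmt1, Dnmt3a and Dnmt3b (triple knockout, TKO). Cytoplasmic RNA was used, per the labels' protocols. The ES cells grew without feeders on gelatin with LIF, per the labels' protocols, WT cells (line J1) in medium with serum replacement and TKO cells in medium with fetal calf serum. Flk1+ cells were sorted with an antibody after 4.5 to 5 days on OP9 stromal cells in serum medium, and ntTS cells grew with FGF4 and heparin on embryonic fibroblasts and were sorted by GFP to leave the fibroblasts behind, per the labels' protocols. ES and Flk1+ samples came from 1 line per genotype, so genotype and line, and in ES cells also the medium, cannot be told apart. ntTS samples came from 2 lines per genotype (WT lines 9.2 and 4.2, TKO lines 1 and 1.4). Each of the 8 groups of genotype, cell type and line had 2 arrays. Nothing in the sources used here says that the 2 came from separate cultures, so p-values measure only the spread between these samples.

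The deposited scanner files hold spot intensity from Agilent Feature Extraction 10.5.1.1, per the file headers. The processed intensity was background-subtracted and detrended within each array, with low values replaced by a surrogate, per the file headers, and not normalized between arrays. The deposited value table holds log2 intensity that was quantile-normalized between the 16 arrays: each column had a median of 4.68, the sorted values of every column lay within 0.0017 of those of the array of WT ES replicate 1, and each column correlated with its own array's log2 processed intensity at 0.9989 or above. This table came from Feature Extraction and limma, per the submitters' processing notes. The limma version and steps are not given in the sources used here. 900 spots other than controls had no value in that table.

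The main values were log2 of the processed intensity minus the array's 75th percentile over spots other than controls (43379 spots). Spots marked as outliers by the scanner software, 65 to 121 per array, were left out, and no spot was saturated. Spots of 1 probe were averaged; 245 probes had 10 spots each. Probes were named through their RefSeq accession for 26690 of 41174 probes, which changed 3169 symbols, and otherwise kept the name in the files. The table used for names belongs to assembly GRCm38.p6 and gave names only; all coordinates are those of the file headers' build, mm9. Of several probes for a gene, the brightest over the 16 arrays stood for it, which gave 28482 gene names. Of 85 further probes tested for named genes that passed, 66 passed in the same direction, 17 did not pass and 2 passed in the opposite direction (Ikzf4 at −1.82 and Ncam1 at 6.61, both in Flk1+ cells).

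Genes were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes, Benjamini-Hochberg adjustment). A gene was tested where its probe was well above background on every array of at least 1 compared group. A gene bright in only 1 group entered through that group, which by itself favours a difference toward it. List tests were not repeated without such genes. A gene passed with an adjusted p under 0.05 and a difference of at least 1 log2 unit. The words rose, fell and changed are used only of genes or lists that passed. ES and Flk1+ comparisons, differences of TKO effects between cell types, Flk1+ against ES cells and line against line came from 1 fit of 8 groups on 16 arrays with 8 residual degrees of freedom. The ntTS genotype comparison used the 8 ntTS arrays with the line as a random block (consensus correlation 0.822). A gene not well above background on any array of a group has only a bound there. For such genes the text gives the bright group over the dim group as "at least N-fold", with each dim array set to the higher of its lowest signal among probes well above background and the probe's own signal. Values "at the limit" are differences of effects with every array set so.

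24 gene lists with 829 entries, 760 of them with a probe, were written before the data were examined: the 3 Dnmt genes, other DNA methylation factors, germline genes, the Rhox homeobox cluster, X-linked cancer-testis type genes, 2-cell-stage type genes, paternally and maternally expressed imprinted genes, pluripotency, trophoblast stem cell, differentiated trophoblast, mesoderm and hemato-vascular, primitive and visceral endoderm, neural, Hox, clustered protocadherin, stromal and fibroblast, interferon-stimulated, p53 target, cholesterol synthesis, BMP and serum response (with immediate early genes), hypoxia and glycolysis, proliferation and Y-linked genes. Lists with at least 5 tested members were set against all other tested genes with limma's cameraPR at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. Adjustment was over 66 list tests for the genotype comparisons, 68 for the differences of effects, and 87 for the cell type and line comparisons. The Dnmt list was too short for that test. Nanog, Fgf4 and Prdm14 had no matching probe and were not analysed here.

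The rule for named genes took, in each genotype comparison, the 8 highest and 6 lowest genes with a gene symbol that passed and whose arrays did not overlap, and up to 2 members per direction of each list, those with the smallest adjusted p. It added the 12 genes with the largest smallest difference among those higher in all 3 cell types, the 4 highest and 4 lowest for each difference of effects, the 5 highest and 5 lowest for Flk1+ against ES cells (with members of the mesoderm, pluripotency and endoderm lists), and the 3 highest and 3 lowest between lines. Dnmt1, Dnmt3a, Dnmt3b, Xist, H19 and Rhox5 were named whatever their values. Genes named outside this rule are said to be so.

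The 16 arrays lay on 5 slides, scanned in 7 passes. Slide 1 held 1 array of each ES and Flk1+ group, slide 2 held 1 array of each ntTS line, slide 3 held the other ES arrays, slide 4 held the other Flk1+ arrays with the other WT ntTS arrays, and slide 5 held the other TKO ntTS arrays. The design, the lists, the named-gene rule, the thresholds and the alternatives were fixed before the data were examined, except 2 alternatives chosen after seeing the data: slide by scan pass as a block, and genes of chromosomes 8, 11 and 14 left out. An alternative called normexp below changed the background correction and the normalization together (normexp with offset 50, then quantile normalization). Other alternatives changed the normalization alone (quantile, median centring, deposited log2 values), the filter on dim probes, the outlier spots, the choice of probes, the thresholds, the variance trend, the arrays in the fit, the slide block, the handling of ntTS lines, each line and each array left out, and a block by replicate number. The steps were tested on simulated data with 50 genes changed at each of 4 sizes. For ES cells (15200 genes) 44.0% of genes changed by 1 log2 unit and 90.0% of those changed by 2 passed, with 1 of 15000 unchanged genes; for Flk1+ cells (15157 genes) 40.0%, 98.0% and 2 of 14957; for ntTS cells (15033 genes) 30.0%, 70.0% and 4 of 14833; and for the difference of Flk1+ and ES effects (16288 genes) 40.0%, 84.0% and 3 of 16088. The simulated lines differed from each other only in ntTS cells. In ES and Flk1+ cells the counts of unchanged genes that passed therefore leave out differences between the WT and TKO parent lines. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with the R package data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6.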

Results

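Messenger RNA levels were measured in 16 mouse cell samples, 1 array each, from cells with or without the DNA methyltransferases Dnmt1, Dnmt3a and Dnmt3b. The samples formed 8 groups of 2 arrays: WT and TKO ES cells, WT and TKO Flk1+ mesoderm cells sorted after differentiation of those ES cells, WT ntTS lines 9.2 and 4.2, and TKO ntTS lines 1 and 1.4. Between 50.8% and 55.3% of spots per array were well above background. The 75th percentile of processed intensity ran from 329 to 473 and the median from 19 to 29.5, and the number of arrays limits the precision of every value. Levels below are log2 intensity relative to the array's 75th percentile. Pluripotency genes averaged 3.70 ± 0.00 (SD, n = 2) in WT ES cells and 3.66 ± 0.00 (SD, n = 2) in TKO ES cells, against −0.40 ± 0.02 (SD, n = 2) in WT Flk1+ cells. Trophoblast stem cell genes averaged 3.18 ± 0.03 (SD, n = 2) in WT ntTS line 9.2 and 2.94 ± 0.03 (SD, n = 2) in TKO ntTS line 1.4, against −1.13 in WT ES cells. Over 16892 genes, arrays of 1 group correlated at 0.991 to 0.995, arrays of 1 cell type and opposite genotype at 0.941 to 0.969, and arrays of different cell types at 0.840 to 0.880. Arrays of different ntTS lines of 1 genotype correlated at 0.974 to 0.991. These are correlations across genes, which are not independent replicates.

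The 3 targeted genes were lower on every TKO array than on every WT array of the same cell type. In ES cells Dnmt1, which copies methylation onto newly made DNA, was at −1.52 ± 0.01 (SD, n = 2) in TKO and 3.40 ± 0.03 (SD, n = 2) in WT cells (adjusted p = 2.7e-09). Dnmt3a, which methylates unmethylated DNA, was at −3.87 ± 0.06 against 3.34 ± 0.02 (SD, n = 2; adjusted p = 2.7e-09), and Dnmt3b, with the same activity, was at −0.39 ± 0.05 against 4.37 ± 0.00 (SD, n = 2; adjusted p = 1.3e-10). In Flk1+ cells the differences were −4.82 for Dnmt1, −6.23 for Dnmt3a and −3.74 for Dnmt3b, with adjusted p = 5.5e-10, 1.3e-09 and 1.2e-10. In ntTS cells they were −3.84 ± 0.14, −4.86 ± 0.26 and −4.08 ± 0.19 (SE, n = 4 arrays from 2 lines per genotype), with adjusted p = 2.8e-06, 2.0e-05 and 9.2e-06. The probes lay, in mm9, on chromosome 9 between 20711973 and 20712341 (Dnmt1), on chromosome 12 between 3906868 and 3907649 (Dnmt3a) and on chromosome 2 between 153513083 and 153513142 (Dnmt3b). Whether they lie inside the deleted parts is not given in the sources used here, so they check the labels only as far as the transcript level goes. At these probes TKO signal stayed well above background except for Dnmt3a on 2 of the 4 TKO ntTS arrays. The 2 other Dnmt3a probes were well above background on every WT array and on 0 of the 8 TKO arrays.

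**Figure D1:**
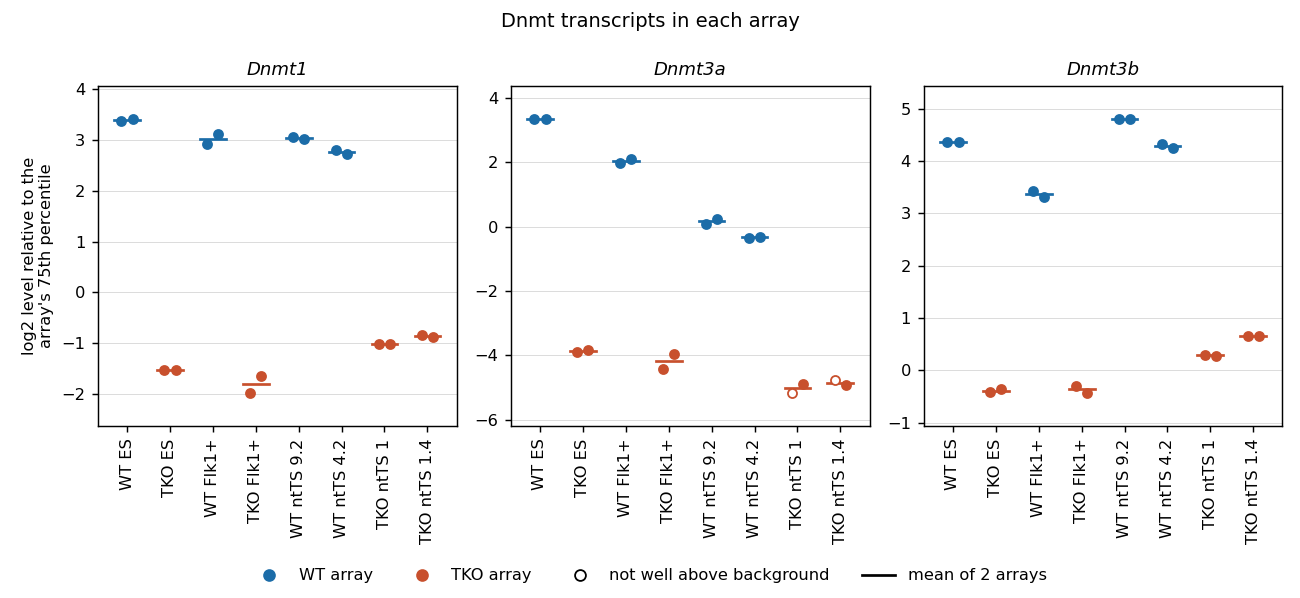
Log2 level of Dnmt1, Dnmt3a and Dnmt3b relative to each array's 75th percentile (vertical axis) in the 8 groups (horizontal axis); points are arrays, lines are means of 2 arrays, and open points were not well above background. In ES cells Dnmt3a was at 3.34 in WT and −3.87 in TKO cells, and in each cell type all TKO points lie below all WT points.

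TKO ES cells were compared with WT ES cells to find genes that differ in undifferentiated cells without the 3 enzymes. Id1 and Id2, which block DNA binding of basic helix-loop-helix factors and answer to BMP and serum, rose by 3.67 ± 0.06 and 3.98 ± 0.09 log2 units (SE, n = 2 per genotype), with Id1 at 4.74 ± 0.08 in TKO and 1.07 ± 0.03 in WT cells (SD, n = 2). The medium held serum for TKO and serum replacement for WT ES cells. The vascular factor gene Sox18 rose by 3.0 ± 0.16, the endoderm factor gene Sox17 at least 6.86-fold and the neurofilament gene Nefm by 4.44 ± 0.26 (SE). Asz1, which protects germ cells from transposons, rose at least 5.20-fold (adjusted p = 3.2e-09), its probe lying on chromosome 6 between 18005508 and 18021991 in mm9. The imprinted growth factor gene Igf2 fell by 2.94 ± 0.19 log2 units and its imprinted neighbour H19 rose by 4.16 ± 0.24 (SE; adjusted p = 2.0e-06 and 8.9e-07). The collagen genes Col1a1 and Col1a2 fell by 3.01 ± 0.22 and 3.84 ± 0.32, and Stra8, needed for entry into meiosis, fell by 4.62 ± 0.44 (SE). Other genes with the largest increases were Enpp2 (5.11 ± 0.48, SE), Slpi (at least 7.60-fold), Fam162b (at least 10.1-fold), Slco2a1 (at least 17.2-fold), Prok2 (at least 4.15-fold) and Coch (4.25 ± 0.49, SE). Enpp2, Nefm and Coch were well above background on 1 of 2 WT arrays. The largest decreases apart from the Dnmt genes were in Pkhd1 (at least 12.2-fold), Xirp2 (at least 8.85-fold) and Nkx6-3 (−5.10 ± 0.34, SE; well above background on 1 of 2 TKO arrays).

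Several fixed groups moved in TKO ES cells. Of 33 mesoderm and hemato-vascular genes 18 rose and 1 (Pecam1, −1.12) fell, with a median of 1.25, or 1.02 with bounded members (adjusted p = 4.5e-07, and adjusted p = 0.046 with an estimated correlation). No other list kept its call with an estimated correlation in ES cells. Of 34 primitive and visceral endoderm genes 19 rose and 1 (Hnf4a, at least 3.35-fold) fell. The median was 1.24, or 1.09 bounded (adjusted p = 1.9e-07, but adjusted p = 0.11 with an estimated correlation). BMP and serum response genes rose in 9 of 34 and fell in 0. The median was 0.39 (adjusted p = 2.0e-07, but adjusted p = 0.15 with an estimated correlation). Hypoxia and glycolysis genes, such as Egln3 (1.49) and Pgk1 (1.09), rose in 10 of 30 and fell in 1, Adm (−1.70). The median was 0.56 (adjusted p = 9.6e-05, but adjusted p = 0.21 with an estimated correlation). Trophoblast stem cell genes, among them Gata3 (2.61), rose in 9 of 28 and fell in 0. The median was 0.43 (adjusted p = 6.7e-04, but adjusted p = 0.14 with an estimated correlation). Interferon-stimulated genes rose in 9 of 32, for example Ifitm1 (3.14) and Psmb8 (2.89), and fell in 2, Eif2ak2 (−1.06) and Oasl1 (−1.69). The median was 0.32 (adjusted p = 0.0047, but adjusted p = 0.63 with an estimated correlation). Germline genes rose in 9 of 48 and fell in 6, including Sohlh2 (−1.53). The median was 0.40 (adjusted p = 0.0062, but adjusted p = 0.14 with an estimated correlation). X-linked cancer-testis type genes, such as Mageb4 (1.82) and Xlr4b (1.78), rose in 7 of 12 and fell in 0. The median was 1.80, or 1.42 bounded (adjusted p = 0.0085, but adjusted p = 0.14 with an estimated correlation). Paternally expressed imprinted genes rose in 9 of 26, among them Magel2 (3.30) and Plagl1 (3.03), and fell in 3, including Sfmbt2 (−1.86). The median was 0.88 (adjusted p = 0.046, but adjusted p = 0.20 with an estimated correlation). Cholesterol synthesis genes fell in 2 of 31, Pcsk9 (−1.65) and Msmo1 (−1.14), and rose in 0. The median was −0.49 (adjusted p = 3.6e-05, but adjusted p = 0.20 with an estimated correlation). p53 targets, among them Gdf15 (−2.33) and Psrc1, fell in 6 of 35 and rose in 0. The median was −0.35 (adjusted p = 0.0011, but adjusted p = 0.21 with an estimated correlation).

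The other lists did not pass in ES cells. Pluripotency genes rose in 1 (Lefty2, 1.78) and fell in 1 (Tbx3, −1.33) of 30 (median −0.11, adjusted p = 0.57). Stromal and fibroblast genes rose in 5 of 32, including S100a4 (2.51), and fell in 7, including the 2 collagen genes (median −0.33, adjusted p = 0.38). Neural genes rose in 10 of 20, for example Foxg1 and Nes (1.92), and fell in 3, including Ncam1 (−2.01). The median was 1.05, or 0.81 bounded (adjusted p = 0.33). Maternally expressed imprinted genes rose in 7 of 24, including Calcr (3.26), and fell in 2, Kcnq1 (at least 1.48-fold) and Tspan32 (−1.02), with a median of −0.05 but a mean of 0.34 and a test pointing up (adjusted p = 0.34). Rhox genes rose in 2 of 6, Rhox2a (2.62) and Rhox4e (2.26), with a median of 0.29 (adjusted p = 0.21; normexp brought this list past the threshold), and Rhox5 itself was at −0.32 ± 0.12 (SE; adjusted p = 0.056). Counts were 6 higher and 3 lower of 14 differentiated trophoblast genes (median 0.07, adjusted p = 0.75), 4 and 3 of 14 Hox genes (0.15, adjusted p = 0.91), 1 and 2 of 11 2-cell-stage type genes (−0.03, adjusted p = 0.68), 1 and 0 of 7 Y-linked genes (0.27, adjusted p = 0.26), 0 and 1 of 26 DNA methylation factors (0.12, adjusted p = 0.96), 0 and 0 of 34 proliferation genes (0.12, adjusted p = 0.33) and 0 and 0 of 4 clustered protocadherins (0.23, too few to test). Counts adjusted over the list alone equalled these in every list in ES cells. With limma, 2044 of 15238 genes passed, 1277 higher and 767 lower (62.5% higher), and median centring gave 1068 higher and 1038 lower (50.7%) while moving the median of all genes from 0.02 to −0.13. With the slide as a block 2013 genes passed. List medians on slides 1 and 3 were 1.24 and 1.37 for mesoderm, 1.25 and 1.2 for endoderm, 0.36 and 0.43 for BMP and serum response, 0.58 and 0.55 for hypoxia, 0.43 and 0.43 for trophoblast stem cell, 0.38 and 0.26 for interferon, 0.45 and 0.42 for germline, 1.60 and 1.88 for cancer-testis, 0.86 and 0.78 for paternally expressed imprinted, −0.49 and −0.48 for cholesterol and −0.43 and −0.40 for p53 genes. The slide block ended the call of the paternally expressed imprinted list and normexp that of the germline list (median 0.22), and WT and TKO ES cells also differed in line and medium.

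**Figure D2:**
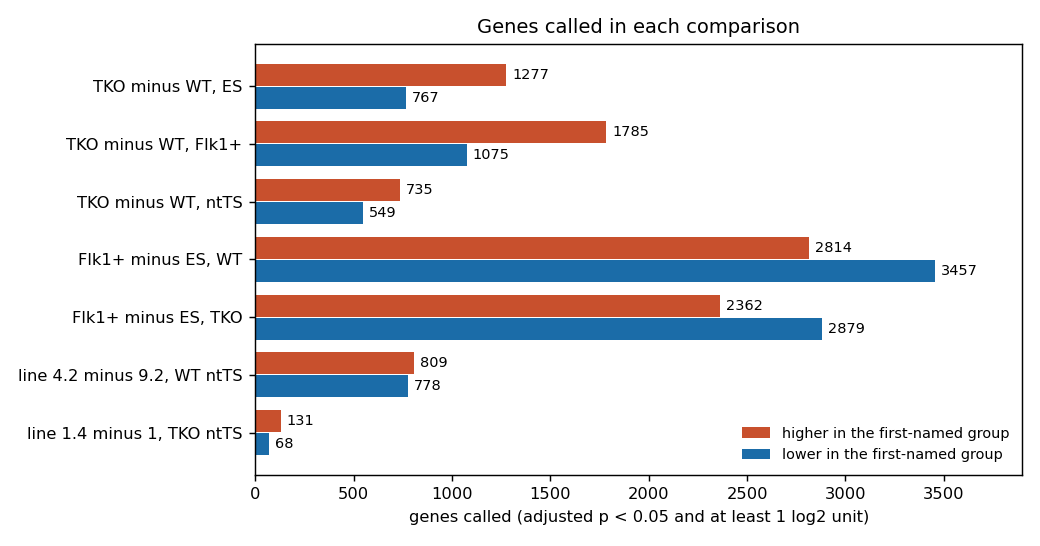
Number of genes that passed (adjusted p under 0.05 and at least 1 log2 unit; horizontal axis) in each comparison (vertical axis), with bars for genes higher and lower in the group named first. TKO Flk1+ cells had 1785 higher and 1075 lower genes, and the TKO ntTS lines differed from each other in 199.

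TKO Flk1+ mesoderm cells were compared with WT Flk1+ cells to find genes that differ after differentiation without the 3 enzymes. Genes of the germline and of X-linked testis and Rhox clusters were among those that rose most in TKO cells: Rhox2a, a homeobox gene of the X chromosome, rose at least 542-fold (4.39 ± 0.29 against −6.92 ± 0.11, SD, n = 2; adjusted p = 4.7e-11), its probe lying on chromosome X between 34785561 and 34785620 in mm9. Xlr4b and Xlr5a, X-linked genes of the Xlr family, rose at least 789-fold and at least 270-fold, and the germ cell gene Tex19.1 rose by 7.27 ± 0.11 (SE; adjusted p = 5.4e-11). Rhox5, the founding member of its cluster, was at 7.15 ± 0.26 in TKO and 1.27 ± 0.15 in WT cells (SD, n = 2; adjusted p = 6.0e-10). Igf2 fell by 6.68 ± 0.19 and the imprinted growth inhibitor gene Grb10 by 5.54 ± 0.17 (SE; adjusted p = 5.2e-09 and 8.3e-09), while H19 rose by 3.57 ± 0.24 (SE; adjusted p = 9.7e-07). The receptor gene Kdr, which encodes the Flk1 protein used for sorting, fell by 1.2 ± 0.08, and the growth factor gene Bmp4 fell by 2.70 ± 0.09 (SE). Chrna10 (at least 207-fold), Xlr3c (at least 332-fold), Rpl39l (at least 198-fold), Rhox13 (at least 218-fold) and Fkbp6 (at least 111-fold), a meiosis gene, were among the 8 genes with the largest increases, and Trim55 (at least 13.2-fold) and the imprinted Zim1 (at least 6.85-fold) were among the genes with the largest decreases.

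Germline genes rose in 31 of 41 and fell in 0 (32 and 0 adjusted over the list alone), with a median of 3.26, or 1.84 with 26 bounded members (adjusted p = 1.1e-57, and adjusted p = 0.0027 with an estimated correlation). On both arrays 14 germline genes were well above background in WT and 41 in TKO Flk1+ cells. The counts were 2 and 9 for cancer-testis, 2 and 7 for Rhox, 2 and 6 for 2-cell-stage type and 2 and 5 for Y-linked genes. Most tested members of these lists thus entered through TKO cells alone and could hardly fall, so the filter itself favours their rise. X-linked cancer-testis type genes rose in 8 of 9. The median was 5.44, or 5.34 bounded (adjusted p = 7.2e-42, and adjusted p = 0.018 with an estimated correlation). All 7 Rhox genes rose, including Rhox6 at least 30.4-fold. The median was 6.93, or 5.83 bounded (adjusted p = 3.8e-26, but adjusted p = 0.092 with an estimated correlation). Hypoxia and glycolysis genes fell in 21 of 30 and rose in 0, with Ndrg1 at −3.27 ± 0.10 and Ero1a at −2.33 ± 0.07 (SE) as examples. The median was −1.34 (adjusted p = 3.9e-26, and adjusted p = 0.034 with an estimated correlation). Interferon-stimulated genes rose in 28 of 36, among them Ifi27 (5.81), Parp14 (at least 13.7-fold) and Isg15 (4.04), and fell in 1, Mx1 (at least 2.79-fold). The median was 2.02, or 1.87 bounded (adjusted p = 4.8e-14, but adjusted p = 0.13 with an estimated correlation). p53 targets rose in 14 of 33 and fell in 0, for example the stress genes Sesn2 (1.98) and Trp53inp1 (1.84). The median was 0.65 (adjusted p = 7.7e-04, but adjusted p = 0.27 with an estimated correlation). Maternally expressed imprinted genes rose in 5 of 24 and fell in 7, among them Igf2r (−2.16). The median was −0.23 (adjusted p = 0.0047, but adjusted p = 0.40 with an estimated correlation). 2-cell-stage type genes rose in 4 of 6 and fell in 0, including Usp17la at least 38.9-fold. The median was 3.64, or 1.89 bounded (adjusted p = 0.0027, but adjusted p = 0.14 with an estimated correlation). Y-linked genes rose in 3 of 5 and fell in 0, including Kdm5d at least 3.62-fold and Usp9y at least 2.83-fold. The median was 3.25, or 1.5 bounded (adjusted p = 0.0019, but adjusted p = 0.13 with an estimated correlation). Stromal and fibroblast genes, markers of the OP9 cells used for culture and of other mesenchyme, rose in 13 of 36 and fell in 0, for example Timp1 (1.65) and Ccn1 (2.35). The median was 0.86, or 0.84 bounded (adjusted p = 0.33). They averaged −0.03 ± 0.30 in TKO and −0.76 ± 0.14 in WT Flk1+ cells (SD, n = 2), beside the gains in interferon and p53 genes and the losses in hypoxia genes.

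Mesoderm and hemato-vascular genes fell in 10 of 47 and rose in 3, Meox1 (2.30) and Meis1 (1.24) among the latter (median −0.43, adjusted p = 0.061; normexp brought this list past the threshold). Pluripotency genes rose in 5 of 27, including Dppa5a (3.0), and fell in 3, including Esrrb and Sall4 (−1.2), with a median of 0.06 (adjusted p = 0.97; median centring turned the median negative). Trophoblast stem cell genes rose in 5 and fell in 8 of 26 (−0.43, adjusted p = 0.16; normexp brought this list past the threshold). Endoderm genes rose in 6, including Afp at least 8.17-fold, and fell in 2 of 32, Foxa2 (−1.44) and Sox7 (−1.29). The median was 0.13 (adjusted p = 0.75). DNA methylation factors rose in 1, Dnmt3l (2.61), a cofactor of the Dnmt3 enzymes, and fell in 3 of 25, including the demethylation genes Tet1 (−1.99) and Tet2 (−2.59). The median was −0.11 (adjusted p = 0.71). Paternally expressed imprinted genes rose in 5 and fell in 3 of 27 (0.40, adjusted p = 0.99), Hox genes rose in 5 and fell in 6 of 17 (−0.48, adjusted p = 0.99), and neural genes rose in 8 and fell in 3 of 17 (0.31, adjusted p = 0.23). BMP and serum response genes rose in 10, including Socs3 (1.62), and fell in 4 of 35 (0.40, adjusted p = 0.38). Proliferation genes rose in 2 of 34, Ccne1 (2.19) and Rrm2 (1.19). The median was 0.16 (adjusted p = 0.82). Differentiated trophoblast genes rose in 2 and fell in 5 of 13 (−0.90, adjusted p = 0.75), and neither cholesterol synthesis genes (0 of 31, median −0.11, adjusted p = 0.36) nor clustered protocadherins changed (0 of 7, median 0.04 with a test pointing down, adjusted p = 0.86). The brightest Xist probe was well above background on both arrays of TKO Flk1+ cells and of no other group, at least 1.55-fold above WT (adjusted p = 0.078). Another Xist probe passed, at 3.52 (adjusted p = 9.4e-07), and 2 further probes were too dim to test. Counts adjusted over the list alone equalled those given for every list but the germline list. With limma, 2860 of 15194 genes passed, 1785 higher and 1075 lower (2827 with the slide as a block). Median centring gave 1575 higher and 1290 lower. List medians on slides 1 and 4 were 3.44 and 3.76 for germline, 7.01 and 4.28 for cancer-testis, 7.41 and 6.46 for Rhox, −1.35 and −1.31 for hypoxia, 1.89 and 2.40 for interferon, 0.66 and 0.71 for p53, −0.18 and −0.27 for maternally expressed imprinted, 3.13 and 3.94 for 2-cell-stage type, 3.40 and 3.10 for Y-linked and 0.80 and 0.82 for stromal genes, and no call of these lists was lost with the slide block. Chromosome 11 had a median of 0.18 in this comparison, with 177 of the 1785 higher calls.

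**Figure D3:**
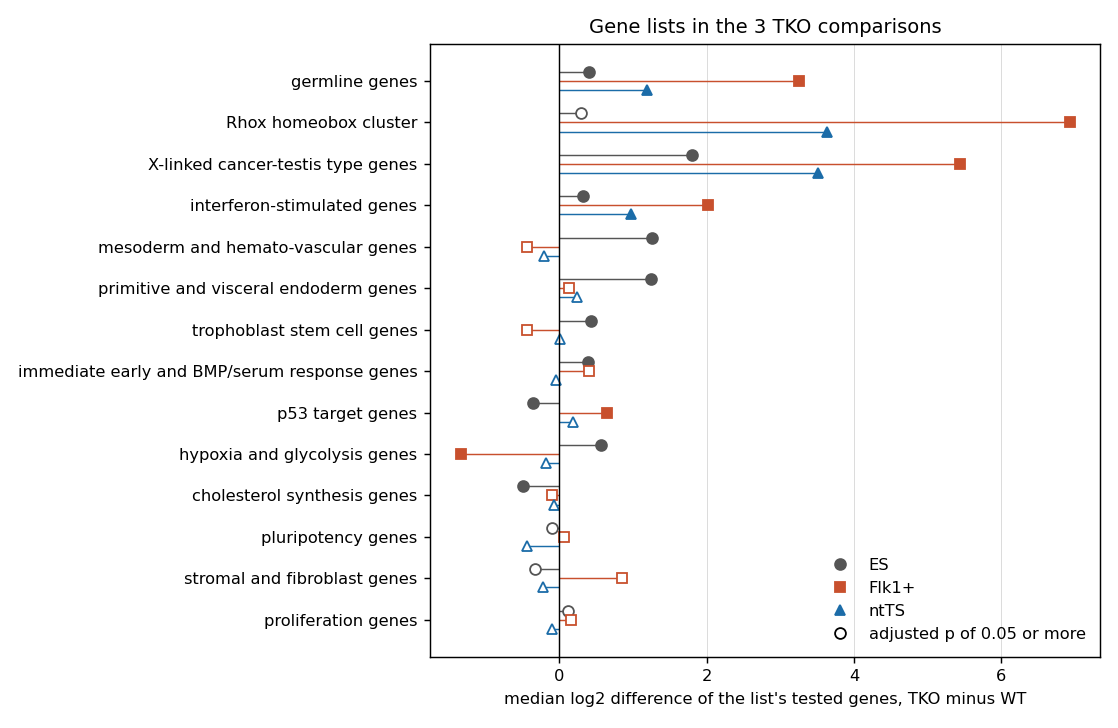
Median log2 difference, TKO minus WT, of the tested members of 14 gene lists (horizontal axis) in ES, Flk1+ and ntTS cells; filled symbols mark lists with an adjusted p under 0.05. Rhox genes had a median of 6.93 in Flk1+ cells, and hypoxia and glycolysis genes had medians of 0.56 in ES and −1.34 in Flk1+ cells.

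TKO ntTS cells were compared with WT ntTS cells to ask the same of an extraembryonic lineage, with 2 lines per genotype. H19 rose by 11.41 ± 0.53 (SE), from −3.93 ± 0.70 to 7.47 ± 0.11 (SD, n = 4; adjusted p = 9.2e-06), and Igf2 fell by 10.19 ± 0.53 (SE), from 8.06 ± 0.28 to −2.13 ± 0.75 (SD, n = 4; adjusted p = 2.0e-05); their probes lie on chromosome 7 between 149761769 and 149761828 and between 149836673 and 149836709 in mm9. The imprinted genes Phlda2 and Cdkn1c, which limit placental and embryonic growth, differed by −6.78 ± 0.38 and −6.63 ± 0.41. The imprinted noncoding RNA Rian rose by 6.50 ± 0.63 (SE; well above background on 3 of 4 WT arrays). Rhox13 rose at least 682-fold (adjusted p = 3.6e-07), the germline genes Fkbp6 at least 93.6-fold and Gpat2 by 6.09 ± 0.17 (SE), and Nlrp4c at least 97.4-fold. The endoderm factor Gata6 fell by 4.89 ± 0.29 and the placental homeobox gene Esx1 by 3.64 ± 0.15 (SE; adjusted p = 4.2e-05 and 5.2e-06), Gata6 being well above background on 1 of 4 TKO arrays. Rhox5 was at 8.80 ± 0.04 in TKO and 8.77 ± 0.10 in WT ntTS cells (SD, n = 4; adjusted p = 0.92), a difference whose sign varied with the scaling. Efhc2 (at least 73.7-fold), Cdh4 (at least 54.6-fold), Rpl39l (8.90 ± 0.95, SE; well above background on 1 of 4 WT arrays) and Rhox2a (7.21 ± 0.47, SE) also rose, and Crym (at least 16.3-fold) and Unc45b (at least 17.2-fold) fell.

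Germline genes rose in 14 of 38 and fell in 1, Tdrd1 (−3.71; well above background on 2 of 4 TKO arrays), or 17 and 1 adjusted over the list alone. The median was 1.19, or 0.71 bounded (adjusted p = 1.7e-22, and adjusted p = 0.021 with an estimated correlation). Against WT line 9.2 it was 1.63 and 1.87, but against WT line 4.2 it was 0.63 and 0.39 (TKO lines 1 and 1.4). X-linked cancer-testis type genes, among them Xlr5a (4.88) and Mageb4 (at least 5.95-fold), rose in 11 of 15, or 14 adjusted over the list alone. The median was 3.52, or 1.97 bounded (adjusted p = 6.5e-35, and adjusted p = 0.018 with an estimated correlation). Rhox genes rose in 5 of 7 and fell in 1, Rhox4e (−1.35). The median was 3.64 (adjusted p = 6.1e-16, but adjusted p = 0.11 with an estimated correlation). By line the Rhox median was 2.54 and 2.63 against WT line 9.2 and 5.13 and 5.38 against WT line 4.2 (TKO lines 1 and 1.4). Interferon-stimulated genes rose in 15 of 37, or 16 adjusted over the list alone, among them Rtp4 (3.60) and Dhx58 (2.04), and fell in 0. The median was 0.98 (adjusted p = 1.8e-12, but adjusted p = 0.11 with an estimated correlation). Hox genes fell in 5 of 24 and rose in 0, including Hoxa7 (−3.57) and Hoxa10 at least 3.11-fold. The median was −0.78, or −0.36 bounded (adjusted p = 0.0087, but adjusted p = 0.47 with an estimated correlation). It was −1.25 and −1.23 against WT line 4.2 but −0.53 and −0.29 against WT line 9.2 (TKO lines 1 and 1.4). Neural genes fell in 5 of 16 and rose in 0, for example Lhx5 (−3.96) and Zic1 (−2.87; well above background on 2 of 4 TKO arrays), with a median of −0.55, or −0.35 bounded (adjusted p = 0.036, but adjusted p = 0.15 with an estimated correlation), and this call was lost with quantile normalization, normexp and the deposited log2 values. Y-linked genes rose in 3 of 6 and fell in 0, including Ube1y1 at least 29.7-fold (median 3.09, bounded 2.10; adjusted p = 0.020, but adjusted p = 0.14 with an estimated correlation). In WT line 9.2, 1 of 7 Y-linked genes was well above background on both arrays. The Y-linked median was 3.63 and 4.94 against WT line 9.2 but 1.05 and 1.35 against WT line 4.2 (TKO lines 1 and 1.4). Maternally expressed imprinted genes rose in 5 and fell in 3 of 21, or 5 and 6 adjusted over the list alone, with a median of −0.03, a mean of 0.20 and a test pointing down (adjusted p = 0.86). Paternally expressed imprinted genes, among them Rasgrf1 (at least 3.91-fold lower) and Snurf (3.0; well above background on 2 of 4 WT arrays, call lost with the slide as a block), rose in 3 and fell in 3 of 23, or 7 and 3 adjusted over the list alone, with a median of 0.27, a mean of −0.03 and a test pointing down (adjusted p = 0.97).

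Trophoblast stem cell genes rose in 1 and fell in 4 of 31, with a median of 0.01, a mean of −0.15 and a test pointing down (adjusted p = 0.069; the slide block turned the median negative). Pluripotency genes rose in 2, Zfp42 (1.04) and Dppa5a (1.79), and fell in 2 of 25, Lin28a (−2.11) and Tbx3, or 2 and 3 adjusted over the list alone (median −0.44, adjusted p = 0.37). Mesoderm and hemato-vascular genes rose in 2, Eng (3.05) and Cdh5, and fell in 4 of 30, including Nkx2-5 (at least 13.9-fold), or 3 and 5 adjusted over the list alone (−0.21, adjusted p = 0.57). Endoderm genes rose in 4 and fell in 5 of 28, with a median of 0.24, a mean of 0.15 and a test pointing down (adjusted p = 0.64). Stromal and fibroblast genes rose in 1, Pdgfrb (1.06), and fell in 1 of 39, Thy1 (−1.54), or 1 and 0 adjusted over the list alone (−0.22, adjusted p = 0.81). BMP and serum response genes rose in 2 and fell in 3 of 35, including Egr1 (−1.67), or 2 and 5 adjusted over the list alone (−0.05, adjusted p = 0.75). Hypoxia genes fell in 3 of 30 (−0.18, adjusted p = 0.23), p53 targets rose in 1 and fell in 1 of 34 (0.18, adjusted p = 0.38), differentiated trophoblast genes rose in 1 and fell in 1 of 18 (0.18, adjusted p = 0.97), and DNA methylation factors rose in 1 of 25 (median −0.08, mean 0.06, test pointing down, adjusted p = 0.89). None of 34 proliferation genes (−0.10, adjusted p = 0.65), 30 cholesterol synthesis genes (−0.07, adjusted p = 0.97), 4 2-cell-stage type genes (0.51) or 2 protocadherins (0.33) passed, the last 2 lists being too short to test. With limma, 1284 of 15068 genes passed, 735 higher and 549 lower (57.2% higher), against 840 (480 higher, 360 lower) with the slide as a block. Within slide 2 list medians were 1.15 for germline, 3.27 for cancer-testis, 3.77 for Rhox, 0.97 for interferon, −0.95 for Hox, −0.69 for neural and 2.94 for Y-linked genes. Without TKO line 1.4 the count was 461 and without TKO line 1 it was 643, while genes on chromosomes 8 and 14 had medians of 0.54 and 0.42 in this comparison. Chromosome 11 was at −0.43 and −0.36 against WT line 9.2 (TKO lines 1 and 1.4) but at −0.10 and −0.07 against WT line 4.2, where the other chromosomes were at −0.06 and −0.07.

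**Figure D4:**
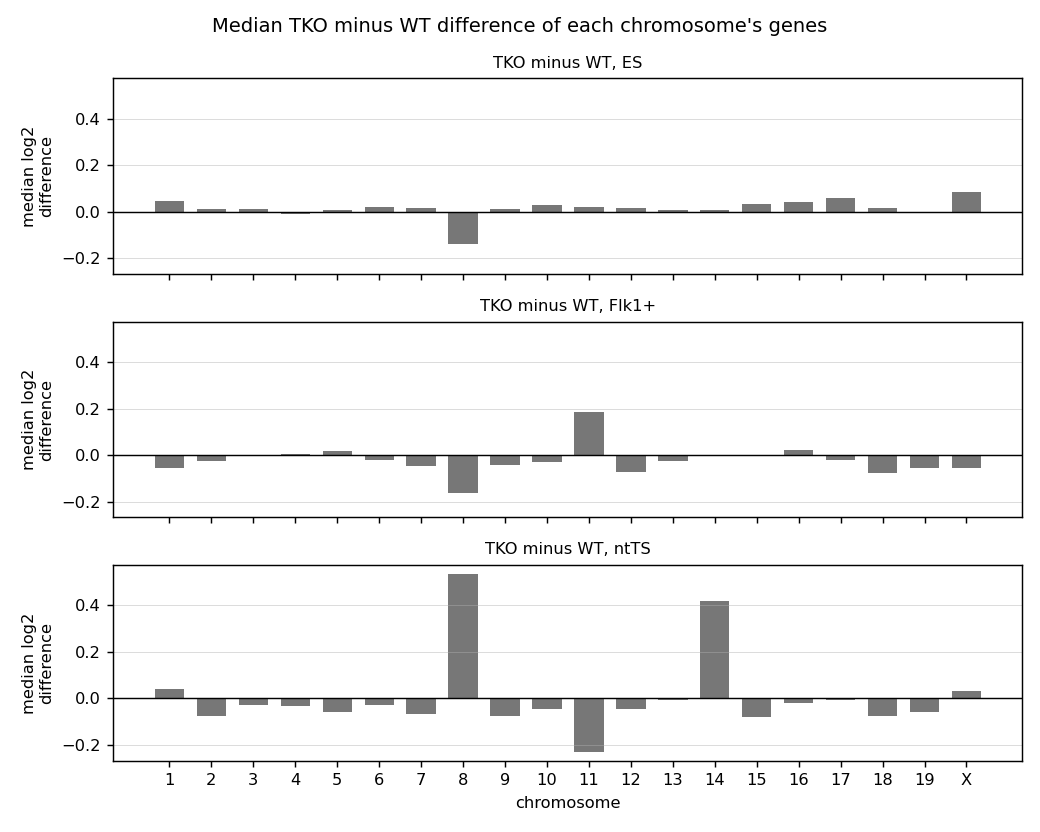
Median log2 difference, TKO minus WT, of the tested genes of each chromosome (horizontal axis) in ES, Flk1+ and ntTS cells. In ntTS cells chromosome 8 had a median of 0.54, and the −0.23 of chromosome 11 went with WT line 9.2 (−0.36 between the WT lines).

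**Figure D5:**
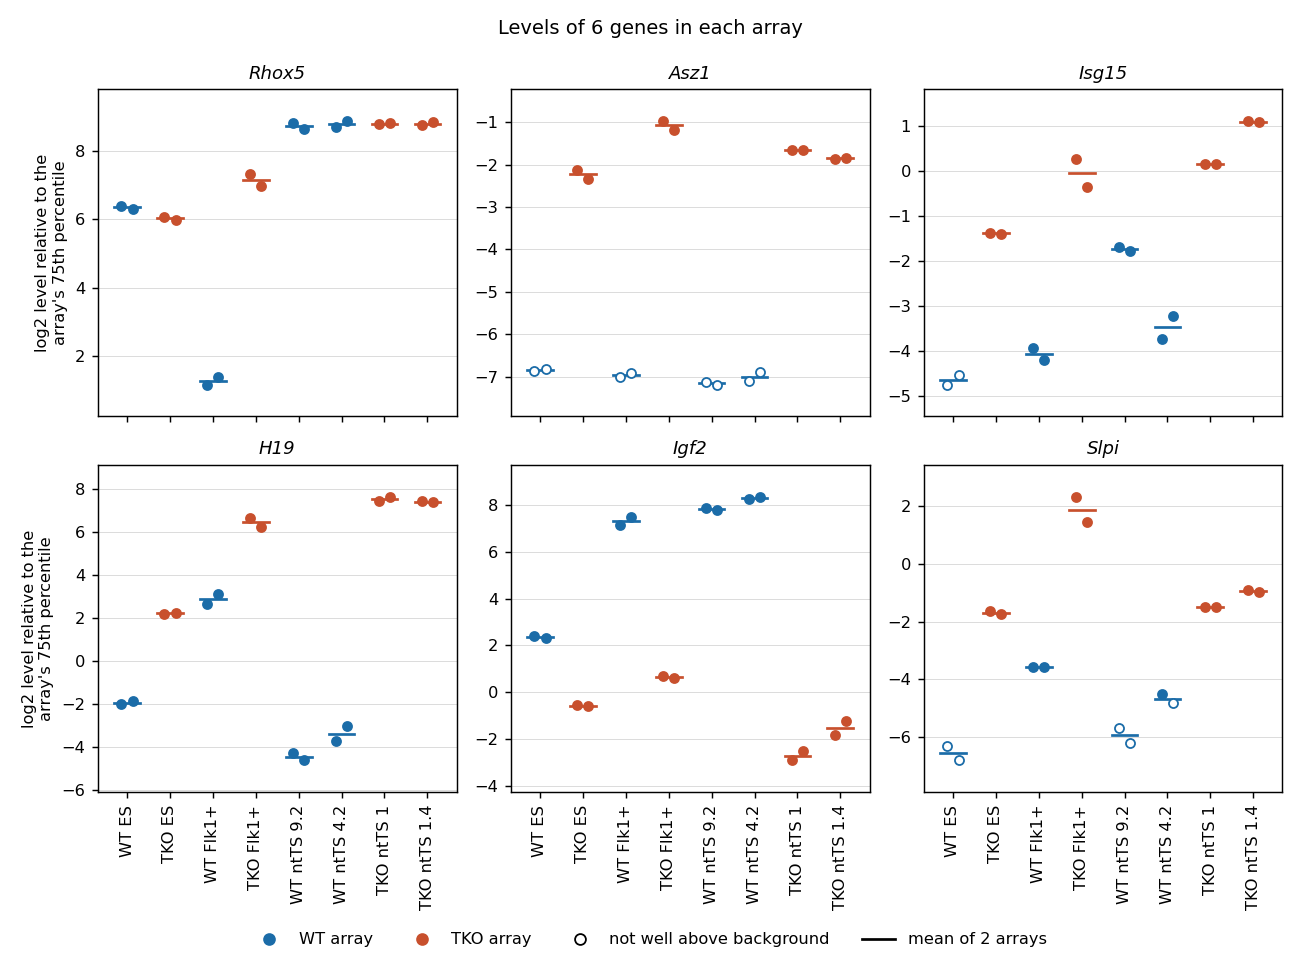
Log2 level relative to each array's 75th percentile (vertical axes) of Rhox5, Asz1, Isg15, H19, Igf2 and Slpi in the 8 groups; points are arrays, lines are means of 2 arrays, and open points were not well above background. H19 was higher and Igf2 lower in TKO than in WT arrays of each cell type, by 11.41 and −10.19 log2 units in ntTS cells.

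Some genes were higher in TKO cells of all 3 types. Asz1 rose at least 5.20-fold in ES, 12.3-fold in Flk1+ and 8.44-fold in ntTS cells. Slpi, a secreted protease inhibitor, rose by 5.48 in Flk1+ and 4.10 in ntTS cells (well above background on 1 of 4 WT ntTS arrays), and the ubiquitin-like interferon target Isg15 by 4.04 and 3.24; both rose in ES cells, at least 7.60-fold and at least 9.36-fold. The immunoproteasome gene Psmb8 rose by 2.89, 2.87 and 4.57 in ES, Flk1+ and ntTS cells, and Chil3, a chitinase-like gene, by 3.03, 8.04 and 3.40. The hexokinase family gene Hkdc1 rose by 3.10 and 4.14 in ES and Flk1+ cells and at least 3.90-fold in ntTS cells, and Hdc, which makes histamine, by 2.92 in ES cells and at least 7.11-fold and 5.48-fold in the others. Gdpd3 rose at least 1.74-fold, by 6.22 and at least 38.5-fold, Gnao1 at least 5.15-fold, at least 4.00-fold and by 4.81 (well above background on 2 of 4 WT ntTS arrays), Ikzf4 at least 3.64-fold, 194-fold and 14.7-fold, and Cyp4a12b at least 2.90-fold, 8.64-fold and 3.57-fold. With H19 these were the 12 gene symbols ranked first by the smallest of their 3 differences, with clone names, Gm numbers and transcript accessions left out. Of those left out, 6 ranked above Psmb8. In all, 75 genes were higher in all 3 types, against 3.88 if the lists were independent, and 14 were lower, against 0.914; 12 of the 75 lie on the X chromosome and 9 belong to the germline, Rhox or cancer-testis lists. Another probe for Ikzf4 passed in the opposite direction in Flk1+ cells (−1.82). The 14 lower genes included the 3 Dnmt genes and Igf2, and, chosen after their values were seen, the prostacyclin synthase gene Ptgis (−1.97, −1.04 and −3.01) and the alkaline phosphatase gene Alpl (−1.73, −1.02 and −1.49).

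By pairs of cell types, 327 genes were higher in both TKO ES and TKO Flk1+ cells, against 112.7 for independent lists, 300 in Flk1+ and ntTS cells, against 66.5, and 139 in ES and ntTS cells, against 46.3. Genes also moved oppositely more often than independent lists would between ES and the other types, with 127 higher in TKO ES and lower in TKO ntTS cells, against 34.3, and 142 lower in TKO ES and higher in TKO Flk1+ cells, against 60.7. The comparisons share no arrays, but ES and Flk1+ cells of a genotype came from the same line. A line difference can thus recur in both, so an excess over independent lists does not by itself show a shared effect of genotype.

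The TKO effects of pairs of cell types were compared to ask where they differ. Germline genes moved up in Flk1+ relative to ES cells in 34 of 51 with 1 lower (median 2.77, at the background limit 1.27; adjusted p = 5.7e-25, and adjusted p = 0.0056 with an estimated correlation) and in ntTS relative to ES cells in 22 of 50 with 6 lower, or 23 and 6 adjusted over the list alone (median 0.82, at the limit 0.46; adjusted p = 1.6e-06, and adjusted p = 0.043 with an estimated correlation), and moved down in ntTS relative to Flk1+ cells in 25 of 46. The median was −1.53 (at the limit −0.96; adjusted p = 8.8e-11, and adjusted p = 0.0095 with an estimated correlation). X-linked cancer-testis type genes moved up relative to ES cells in 7 of 13 with 2 lower in Flk1+ cells, or 7 and 3 adjusted over the list alone (median 2.82, at the limit 0.86; adjusted p = 1.9e-16, but adjusted p = 0.092 with an estimated correlation), and in 10 of 15 in ntTS cells. The median was 1.99 (at the limit 1.14; adjusted p = 1.3e-08, and adjusted p = 0.043 with an estimated correlation). Hypoxia and glycolysis genes moved down in Flk1+ relative to ES cells, 24 of 30 lower and 0 higher (median −1.94; adjusted p = 1.9e-33, and adjusted p = 0.043 with an estimated correlation), and up in ntTS relative to Flk1+ cells, 16 of 30 higher. The median was 1.21 (adjusted p = 1.2e-18, but adjusted p = 0.079 with an estimated correlation). p53 targets moved up in Flk1+ relative to ES cells in 20 of 35 (median 1.37; adjusted p = 1.3e-07, but adjusted p = 0.17 with an estimated correlation), and interferon-stimulated genes in 22 of 38 with 3 lower, or 23 and 3 adjusted over the list alone. The median was 1.51 (at the limit 1.16; adjusted p = 1.1e-05, but adjusted p = 0.28 with an estimated correlation). Mesoderm and hemato-vascular genes moved down relative to ES cells in Flk1+ cells, 23 of 47 lower and 2 higher (24 and 2 adjusted over the list alone; median −1.31, at the limit −1.13; adjusted p = 1.1e-05, but adjusted p = 0.087 with an estimated correlation), and in ntTS cells, 22 of 37 lower and 4 higher (22 and 5 adjusted over the list alone; median −1.63, at the limit −1.22; adjusted p = 1.7e-05, but adjusted p = 0.087 with an estimated correlation). All 7 Rhox genes moved up in Flk1+ relative to ES cells. The median was 7.06 (at the limit 6.11; adjusted p = 1.3e-16, but adjusted p = 0.087 with an estimated correlation). BMP and serum response genes moved down in ntTS relative to ES cells in 11 of 35 with 1 higher (median −0.46; adjusted p = 3.3e-04, but adjusted p = 0.28 with an estimated correlation) and in Flk1+ relative to ES cells in 10 of 36 with 5 higher. The median was −0.26 (adjusted p = 0.032, but adjusted p = 0.56 with an estimated correlation). Stromal and fibroblast genes were lower in ntTS relative to Flk1+ effects in 17 of 40 and higher in 2, or 18 and 2 adjusted over the list alone, and the list did not pass (median −1.24, at the limit −1.11; adjusted p = 0.19). With limma, the effects differed in 4077 of 16327 genes between Flk1+ and ES cells, 2157 higher and 1920 lower, in 3541 of 16225 between ntTS and ES cells, 1679 higher and 1862 lower, and in 3728 of 16272 between ntTS and Flk1+ cells, 1530 higher and 2198 lower. Median centring gave 58.9% higher calls in place of 47.4% between ntTS and ES cells and moved the median of all genes to 0.14. Between ntTS and Flk1+ cells it gave 1896 higher and 1897 lower. These counts, and the list tests of these differences, treat arrays of a line as independent. With the line as a random block 1789 genes differed between ntTS and ES cells and 1978 between ntTS and Flk1+ cells. The list tests were not repeated with that block, so their p-values leave out the spread between ntTS lines.

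Flk1+ cells were compared with ES cells of the same genotype to describe the differentiation itself. In WT cells the mesoderm genes Mesp1 and Kdr rose by 9.92 ± 0.33 and 9.64 ± 0.08 (SE, n = 2 per group), Lhx1 and Prdm6 at least 1135-fold and at least 1286-fold, and the retinoic acid-degrading enzyme gene Cyp26a1 by 9.66 ± 0.18. Stra8 fell at least 618-fold, Khdc3 at least 536-fold, Morc1 at least 365-fold, the pluripotency-associated Nr0b1 at least 344-fold, and Fbxo15, also linked to pluripotency, fell by 9.39 ± 0.08 (SE). In TKO cells Prdm6 rose at least 696-fold, Lhx1 by 10.54 ± 0.21, Asb4 by 9.79 ± 0.20 (SE) and Cer1, an antagonist of Nodal and BMP, at least 97.7-fold, while Nr0b1 fell at least 307-fold and Tdh fell by 8.29 ± 1.04 (SE). Kdr rose by 7.22 in TKO cells and Tbx3 by 1.58 in WT and 2.28 in TKO cells. Mesp1, Kdr and Cyp26a1 were well above background on 1 of 2 WT ES arrays and Lhx1 on 1 of 2 TKO ES arrays.

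Mesoderm and hemato-vascular genes rose in 43 of 47 in WT (median 4.80, bounded 3.91; adjusted p = 3.5e-21) and in 39 of 46 in TKO cells, with 1 lower (median 3.52, bounded 2.84; adjusted p = 5.1e-16), each with adjusted p = 0.021 with an estimated correlation. Pluripotency genes fell in 22 of 30 and rose in 1 in either genotype (medians −4.70 and −4.28; adjusted p = 3.2e-14 and 9.8e-20, but adjusted p = 0.29 with an estimated correlation in each). Germline genes fell in 37 of 44 and rose in 0 in WT cells (median −4.09, bounded −2.97; adjusted p = 1.2e-17, and adjusted p = 0.0058 with an estimated correlation), and fell in 21 and rose in 9 of 50 in TKO cells (median −0.91, adjusted p = 0.23), and the difference between these changes passed for the list (adjusted p = 5.7e-25). Hypoxia and glycolysis genes rose in 24 of 30 in WT cells (median 2.02; adjusted p = 9.8e-20, but adjusted p = 0.073 with an estimated correlation) and in 6 of 30 in TKO cells (median 0.16, adjusted p = 0.17). Endoderm genes rose in 17 and fell in 10 of 35 in WT (median 0.97; adjusted p = 8.4e-04, but adjusted p = 0.29 with an estimated correlation) and rose in 15 and fell in 9 of 36 in TKO cells. The median was 0.41 (adjusted p = 0.043, but adjusted p = 0.29 with an estimated correlation). Stromal and fibroblast genes rose in 19 and fell in 9 of 36 in WT (median 1.33; adjusted p = 0.0058, but adjusted p = 0.47 with an estimated correlation) and rose in 26 and fell in 2 of 37 in TKO cells (median 2.15, bounded 1.82; adjusted p = 2.5e-07, but adjusted p = 0.29 with an estimated correlation), beside the gains of the mesoderm list. With limma, 6271 of 15600 genes passed in WT cells, 2814 higher and 3457 lower, and 5241 of 15809 in TKO cells, 2362 higher and 2879 lower. Median centring turned the larger direction in TKO cells, with 2683 higher and 2553 lower. Both genotypes shared 1472 higher genes, against 364 for independent lists, and 1978 lower genes, against 572. In WT cells the medium also changed from serum replacement to serum, and median differences over all genes were −0.10 and −0.12.

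The 2 lines of each genotype were compared to see how far ntTS lines differ among themselves. In WT cells the Y-linked genes Eif2s3y and Ddx3y were at least 84.4-fold and at least 63.8-fold higher in line 4.2 than in line 9.2, where neither was well above background, and the X-linked Tex13b was at least 61.5-fold higher. Tmem59l was lower in line 4.2 by −5.56 ± 0.15 (SE, n = 2 per line), Baiap3 at least 14.9-fold and Pdk4, a regulator of pyruvate use, at least 7.59-fold. In TKO cells line 1.4 had at least 11.5-fold more Rps6ka6, 6.98-fold more Spaca3 and 4.67-fold more Krt36 than line 1, and at least 10.1-fold less of the glypican gene Gpc3, 3.95-fold less Cuzd1 and 2.88-fold less Olfr713. With limma, 1587 of 14526 genes differed between the WT lines, 809 higher and 778 lower in line 4.2, and 199 of 14427 between the TKO lines, 131 higher and 68 lower in line 1.4. Between the TKO lines 4 genes passed with slide by scan pass as a block and 31 with normexp, and between the WT lines 580 passed with normexp. Median centring gave 38.1% higher calls in place of 51.0% between the WT lines and 54.7% in place of 65.8% between the TKO lines, and moved the median of all genes to −0.14 between the WT lines. Whether the 2 genotypes differ in how unlike their lines are was not tested.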

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

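The tests of earlier expression in ES cells, of noise on the ES arrays and of the culture medium were chosen after the results they bear on had been seen.

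What singled out the results here is a tested difference between 2 cell types in their TKO effects, and groups of 2 arrays were too small for a test of single arrays that stand apart. Most of these differences rest partly on signal below background, so each is followed, where it changes, by its value with every array raised to its background limit, and no order of size is claimed. Between Flk1+ and ES cells the effects differed in 4077 genes. Higher were the X-linked genes Xlr5a (10.52, at the limit 8.28), Rhox13 (8.71, at the limit 7.06) and Rhox2a (8.68, at the limit 6.46) and the ribosomal protein-like gene Rpl39l (9.16, at the limit 7.27). Lower were Gad1, which makes the transmitter GABA (−5.61, at the limit −3.86), the neural factor gene Bhlhe22 (−5.81, at the limit −3.35), Plcxd1 (−6.03, at the limit −5.95) and the Notch ligand gene Dner (−6.10, at the limit −4.88). Germline genes differed by a median of 2.77 (at the limit 1.27) and hypoxia and glycolysis genes by −1.94.

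Between ntTS and ES cells the effects differed in 3541 genes, or 1789 with the line as a random block. Higher were Rhox13 (10.72, at the limit 8.70), Efhc2 (9.21, at the limit 7.02), the cadherin gene Cdh4 (9.11, at the limit 7.25) and Rpl39l (8.54, at the limit 7.68). Phlda2 differed by −7.39, Tmem54 by −7.79 (−3.87 in ntTS and 3.92 in ES cells), the motor neuron factor gene Isl2 by −7.87 (at the limit −7.14) and the membrane traffic gene Mal2 by −8.05 (at the limit −5.86). Germline genes differed by a median of 0.82 (at the limit 0.46) and X-linked cancer-testis type genes by 1.99 (at the limit 1.14).

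Between ntTS and Flk1+ cells the effects differed in 3728 genes, or 1978 with the line as a random block. Higher were H19 (7.84), Cdh4 (7.83, at the limit 5.97), Ly6d (6.56, at the limit 2.97) and the complement gene C2 (6.20, at the limit 5.54). Lower were Usp17la (−6.78, at the limit −5.48), Gtsf1l (−7.22, at the limit −5.54), Tex19.1 (−7.45) and Esx1 (−8.07, at the limit −6.14), and germline genes differed by a median of −1.53 (at the limit −0.96). Ly6d was below background in both Flk1+ groups (TKO effect at the limit −0.06) and Usp17la in every ntTS group (−0.20). Their differences thus rest on the effect in the other cell type.

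Germline genes were called higher in 31 of 41 cases in TKO Flk1+ cells and in 9 of 48 in TKO ES cells. These shares are not alike, since 14 list members were well above background on both WT Flk1+ arrays and 44 on both WT ES arrays. In Flk1+ cells most members were therefore tested through TKO cells alone. Against scaling as the cause, the Flk1+ count was at least 3.33 times the ES count under each of 4 other scalings. Against noise on the ES arrays, the difference of effects passed for the whole list (median 2.77, adjusted p = 0.0056 with an estimated correlation; 1.27 at the background limit, a value with no p of its own), although the higher ES spread between 2 arrays was 1.69 times the lower Flk1+ spread over the list (0.671 times over all genes). Earlier expression in ES cells stays open, since 80.6% of the 31 genes were well above background on both WT ES arrays, against 84.6% of the whole list. That share cannot set the 31 genes apart from a list that was mostly on. Their levels in TKO Flk1+ cells differed from those in WT ES cells by a median of 0.069. Single genes ran from −8.39 (Stra8) to 5.88 (Tex13b). The median thus lay near the WT ES level, while single genes lay far above and far below it. The genes were taken for being higher in TKO Flk1+ cells, so this median does not show a return to ES levels. The part of line and genotype is open too, with 1 line per genotype.

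BMP and serum response genes had a median difference of 0.39 between TKO and WT ES cells, with 9 of 34 higher, and the list lost its call with an estimated correlation (adjusted p = 0.15). Against the slide as the cause, the medians on the 2 slides were 0.358 and 0.427. The medium, which held serum for the TKO line and serum replacement for the WT line, cannot be told apart from genotype and line: the ES median lay 0.445 above the lower and −0.011 from the higher of the medians of the other cell types. No array of WT ES cells in serum medium exists in the series.

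Genes on chromosomes 8 and 14 were higher in TKO ntTS cells, with medians of 0.54 and 0.42 and 118 of the 735 higher calls on chromosome 8. The smaller median exceeded that of all genes by at least 0.360 under 3 other scalings (quantile, normexp, deposited log2 values), all of which include quantile normalization. Scaling acts on the intensities of an array without regard to chromosome, so this check could hardly have pointed to scaling. Against the slide, the medians within slide 2 were 0.403 or more (0.518 for the other chromosome). Each of 4 parts of either chromosome had a median of 0.266 to 0.739, above the limit set beforehand for extra copies. That limit was low and pooled the 2 TKO lines, so passing it does not single out extra copies. Chromosome 14 had medians of 0.21 with TKO line 1 and 0.60 to 0.62 with TKO line 1.4. Copy number was not measured and the part of genotype stays open, with chromosome 8 at −0.14 in ES and −0.16 in Flk1+ cells and chromosome 14 at 0.01 and −0.00 (TKO minus WT).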

How the results depend on the processing

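No result turned its sign past the threshold under any alternative that tested it. Of the 310 results for named genes, 220 kept their call under every alternative in which they were tested, while 89 lost it under at least 1. Id1, Pmaip1 and Snurf in ntTS cells lost theirs most often. With only probes well above background on every array, 170 of the 310 were tested, and 276 with chromosomes 8, 11 and 14 left out. A result not tested there counts as kept. Signal over background limited the values near the floor, where 339 of the higher and 167 of the lower calls in ES cells had a dim side below background. In Flk1+ cells the same held for 611 of the 1785 higher and 175 of the 1075 lower calls. For ntTS cells it held for 184 of the 735 higher and 92 of the 549 lower calls. The cause of the differences below was not tested, except where fewer arrays, fewer genes or a looser threshold entered by construction. The slide by scan pass block and the run without chromosomes 8, 11 and 14 were chosen after seeing the data.

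With normexp and quantile normalization 934 genes passed in ES, 1387 in Flk1+ and 720 in ntTS cells, 2214, 1775 and 1818 for the differences of effects (Flk1+ minus ES, ntTS minus ES, ntTS minus Flk1+), 4072 and 3280 for Flk1+ against ES cells (WT, TKO), 580 between the WT and 31 between the TKO ntTS lines, and 31 were higher in all 3 types. By adjusted p alone, with no size limit, the counts in the same order were 7463, 9562, 2277, 9111, 8677, 9348, 12249, 11606, 7122, 1715 and 278. With only probes well above background on every array they were 1876 in Flk1+ and 852 in ntTS cells, 2459, 1942 and 2058 for the differences of effects, 4135 in WT Flk1+ against ES cells, 114 between the TKO lines and 18 in all 3 types. An adjusted p under 0.01 left 733 in ntTS cells.

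The ntTS count was 840 with the slide as a block, 703 with the scan pass block, 342 within slide 2, 420 with line means, 2020 with lines as fixed groups, 2152 without WT line 9.2, 2089 without WT line 4.2, 643 without TKO line 1 and 461 without TKO line 1.4. With 6 groups and the line as a random block, effects differed in 1789 (ntTS minus ES) and 1978 (ntTS minus Flk1+) genes. The scan pass block left 4 genes between the TKO lines. Genes higher in all 3 types numbered 45 within slide 2, 47 with line means, 48 without TKO line 1 and 42 without TKO line 1.4. Of the 66 gene list tests, 27 passed and 6 passed with an estimated correlation. Without chromosomes 8, 11 and 14 the counts were 1709, 2348 and 975 in ES, Flk1+ and ntTS cells.

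Leaving out 1 array at a time gave 1917 to 1991 genes in ES, 2618 to 2961 in Flk1+ and 1091 to 1205 in ntTS cells, 3836 to 4219, 3313 to 3526 and 3490 to 3860 for the differences of effects, 6088 to 6309 and 5106 to 5218 for Flk1+ against ES cells (WT, TKO), 1449 to 1581 and 140 to 167 between lines (WT, TKO), and 68 to 78 in all 3 types. The lone array left in a group is assumed to vary like the others. With the replicate number as a block the counts were 2024, 2833, 1119, 4042, 3551, 3720, 6312, 5196, 1584 and 190 in that order, 69 in all 3 types and 26 list calls. The call of the paternally expressed imprinted list in ES cells was the 1 lost.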

Other observations

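The ntTS lines differed from each other in gene groups that the text has not yet described. Stromal and fibroblast genes were higher in WT line 4.2 than in line 9.2, with 23 of 39 higher and 1 lower, or 25 and 1 adjusted over the list alone (median 1.30; adjusted p = 8.9e-04, but adjusted p = 0.31 with an estimated correlation). Hox genes, which pattern the body axis, were higher in line 4.2 in 11 of 23 (median 0.81, bounded 0.67; adjusted p = 0.0050, but adjusted p = 0.29 with an estimated correlation). p53 targets were higher in 5 of 34, or 6 adjusted over the list alone (adjusted p = 8.4e-04, but adjusted p = 0.29 with an estimated correlation), and cholesterol synthesis genes lower in 4 of 30 (median −0.41; adjusted p = 8.4e-04, but adjusted p = 0.31 with an estimated correlation). Between the TKO lines, stromal genes were higher in line 1.4 in 4 of 37, or 5 adjusted over the list alone (median 0.68; adjusted p = 2.8e-05, but adjusted p = 0.31 with an estimated correlation), and 0 of 7 Rhox and 0 of 15 cancer-testis genes passed. Stromal genes averaged −1.5 ± 0.00 in WT line 9.2, −0.44 ± 0.13 in WT line 4.2, −1.47 ± 0.03 in TKO line 1 and −0.82 ± 0.20 in TKO line 1.4 (SD, n = 2).

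Of the 35 splits of the 8 ntTS arrays into 4 and 4, only 1, the genotype split itself, reached its own count (1292), and the highest of the others called 1. The 1292 differs from the 1284 of the comparison because the within-line correlation was taken from a sample of genes for the splits. The splits that part a line put both genotypes on each side, which by itself keeps their counts low. Splits that keep each line whole number 3 and are too few for a share under 0.05.

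A hypothesis set out before its test was that genes which ES cells express rise more often in differentiated cells without the enzymes. Of 2422 genes that WT ES cells expressed above WT ntTS cells, 23.9% were higher in TKO Flk1+ cells, against 8.03% of other genes, a ratio of 2.97, and 7.27% against 6.03% were lower. Of 2902 genes that WT ES cells expressed above WT Flk1+ cells, 9.79% were higher in TKO ntTS cells, against 2.83%, a ratio of 3.46, but 6.17% against 2.75% were lower, so these genes moved more often both ways. Both ratios met the prediction made for the higher calls. Genes dim in both genotypes of the differentiated cells were left out, and a gene dim in WT cells was counted only if bright in TKO cells. The filter can by itself raise these ratios, so they do not decide the hypothesis. Whether the genes carry DNA methylation in WT cells was not measured in this series.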
